A study of Mus musculus with 6 samples.

How the data were processed

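The measurement was the abundance of single guide RNAs in mouse embryonic stem cells (129/Ola) that carry a U1-PAS reporter (B2G-U1-PAS in the labels), in a genome-wide CRISPR interference screen. Guide sequences were amplified by PCR from genomic DNA and sequenced. The 6 libraries fall into 3 groups of 2 replicates: unselected cells (day 0) and cells kept in blasticidin for 5 or 8 days. The design text says that 2 separate screens ran side by side. Whether replicate numbers follow the screens, and whether day 8 cells come from the day 5 cultures, is not given in the sources used here. The deposited table holds raw counts of reads per guide for each library, not scaled between libraries. For the submitters' work, the labels name Bowtie 1.3.1, MAGeCK and the mm10 build without saying what each was used for. The design text adds that the submitters compared each selected time with day 0 in MAGeCK. Trimming, mismatches allowed and filters are not given in the sources used here.

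The table lists 107663 guides for 19995 genes, 18415 of which have 5 guides, together with 2168 non-targeting guides. Positions in the guide names were checked against the mouse GRCm38.p6 (mm10) annotation. Of 104706 guides of matched genes, 98.9% lie in the gene or within 1 kb of it. Of the gene names, 18704 matched a current symbol, 1146 matched through a synonym and 145 did not match. Names are printed as the table gives them, with the current symbol where it differs.

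Counts were analysed in R 4.3.3 with edgeR 4.0.16. Guides were kept by filterByExpr with a minimum count of 10, which left 105604 guides and removed 2059. Library sizes were scaled by TMM, and a quasi-likelihood model with 1 term per group was fitted to all 6 libraries. Its F test was run for day 5 against day 0, day 8 against day 0 and day 8 against day 5, two-sided for guides, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes were tested by a rebuilt robust rank aggregation, the kind of gene test that MAGeCK uses. Guides were ranked by their one-sided edgeR p, and ranks within the lowest 25% entered the score. For each number of guides, 2000000 draws of independent random ranks gave a one-sided p, called a gene's permutation p below. No libraries or labels were permuted, so this p takes guides as independent and does not measure the spread between libraries. The smallest p that these draws can give is 5e-07. The 19894 genes with at least 3 tested guides were tested in each direction, and 101 genes with fewer were left out. Non-targeting guides entered the ranking but formed no gene. The value of a gene is the median log2 fold change over its tested guides with the SD over guides, where a guide's fold change is the difference between group means of log2 CPM (scaled counts, TMM, prior count 2). Levels are means over guides, with the SD over the 2 libraries. Summed levels are CPM over all guides of a gene, scaled by the total of the library alone.

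Before the data were examined, 28 gene lists with 1604 members, the tests, the alternatives and the rule for naming genes were fixed. The lists hold U1-specific proteins, U1-associated factors, the pair Zfp207 and Bub3, the Sm ring, SMN assembly, small nuclear RNA transcription and processing, Integrator, U2 snRNP, tri-snRNP, Prp19 and catalytic-step factors, cleavage and polyadenylation, the nuclear exosome with its cofactors, RNA polymerase II elongation, Mediator, mRNA export, nonsense-mediated decay, ribosome rescue with the stress response, LRRC8 volume-regulated channels, chromatin silencing, p53 and growth brakes, pluripotency, the cytosolic ribosome, the proteasome, RNA polymerase II, tRNA synthetases, fibroblast markers, neural and endoderm markers, and olfactory receptors. Lists were tested by camera on ranks in limma 3.58.1, with a preset correlation of 0.01, on all tested guides of their members. The list p compares guides of a list with all other guides, and guides are not independent replicates. An estimated correlation, camera without ranks, the DESeq2 size factors, a filter at a mean of 50 counts, the block and each library left out were the alternatives for lists. The naming rule took the 12 smallest enrichment p and the 6 smallest depletion p at each selected time, the 3 smallest in each direction between the selected times, 3 members of each list, Zfp207, Bub3, the 3 U1-specific proteins, Lrrc8a and Lrrc8d. Ties went to the higher fold change, and named enriched genes had to stand higher in both selected libraries than in both unselected ones. Results of some genes that the rule takes are not reported. Other genes are named as members of a short count or are said to be chosen after their values were seen.

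Alternatives covered DESeq2 1.42.0 for guides, its size factors, scaling by total counts or by non-targeting guides, other count filters, other guide rankings, a rank limit of 10%, counts summed per gene, other thresholds, the replicate number as a block and each library left out. Fits with all libraries but 1 assume that the lone library of a group varies like the others. The main fits have no block, since the design text states none. Tests on simulated counts with no change made 0 gene calls in 3 simulations. With 50 genes changed at each size, the day 5 test recovered 50 of 50 genes raised 16-fold and 36 of 50 raised 4-fold, and the day 8 test recovered 49 and 6. For genes lowered 16-fold it recovered 50 at day 5 and 25 at day 8, and for genes lowered 4-fold 43 and 1. These simulations gave 4 false depletion calls at day 5, and 2 false enrichment calls and 1 false depletion call at day 8. They moved all guides of a changed gene by the same fold, with the same dispersion for all guides of a group. The recovery rates therefore do not cover genes whose guides differ in effect. Figures and rank tests used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

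Library totals ran from 7731687 to 31126058 counts. In the smaller selected libraries a guide with no count may still stand at up to 0.388 CPM, from a floor of 3 counts per library. Such floors and the exact 95% intervals of shares cover counting error only, since PCR reads without molecular identifiers are not independent molecules.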

Results

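Guide RNA abundance was measured in mouse embryonic stem cells (129/Ola) that carried a U1-PAS reporter (the line B2G-U1-PAS) and a genome-wide CRISPR interference library, in which each guide lowers transcription of the gene it is placed at. U1 snRNP recognises 5′ splice sites and also keeps transcripts from being cut and polyadenylated too early. Blasticidin, a drug that blocks protein synthesis, was used to keep cells whose reporter had become more active, and guides were read from 2 libraries each of unselected cells (day 0), cells after 5 days and cells after 8 days. The stated question was which genes act on U1 snRNP and on repression through the U1-PAS element. The unselected libraries held 27278772 and 31126058 counts, the day 5 libraries 9416956 and 7731687 and the day 8 libraries 9723831 and 7816182.

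The library became narrower with time in blasticidin. The 10 most abundant guides took 0.0387% ± 0.0008 of counts at day 0, 3.15% ± 0.178 at day 5 and 43.7% ± 0.767 at day 8 (SD, n = 2). Non-targeting guides held 2.03% ± 0.0035 of counts at day 0, 1.87% ± 0.0249 at day 5 and 0.944% ± 0.114 at day 8 (SD, n = 2). At day 8, 19.6% ± 0.157 of guides had no count (SD, n = 2), against 0.268% ± 0.0205 at day 0. Replicate libraries also moved apart, with a biological coefficient of variation of 23.1% at day 0, 68.6% at day 5 and 141% at day 8. The median guide stood at −0.10 log2 at day 5 and −1.02 at day 8 against day 0 after TMM scaling, and the non-targeting guides at −0.13 and −1.05. Scaling by total counts put the median guide at −0.31 and −2.47, and scaling by non-targeting guides at −0.19 and −1.51. All changes below are read relative to these medians. None of the 6 libraries comes from cells kept without blasticidin to day 5 or day 8. Rises and falls against day 0 therefore hold time in culture as well as selection, which cannot be told apart here.

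**Figure D1:**
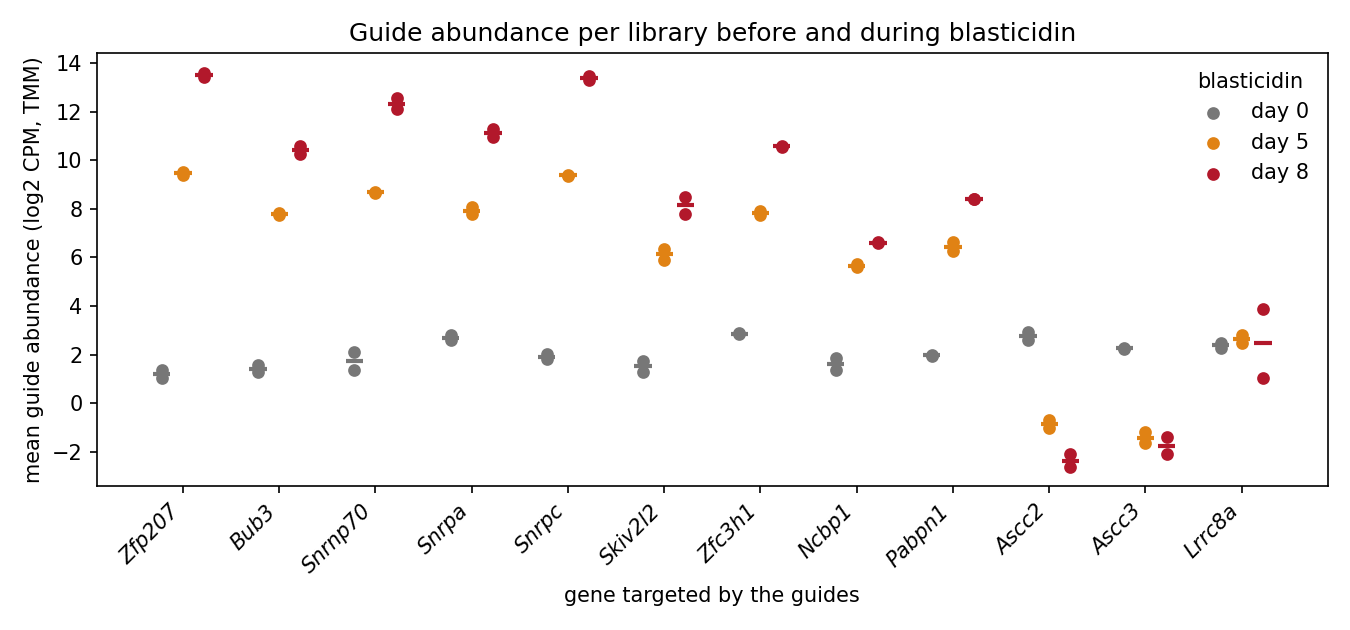
Mean guide abundance (log2 CPM, TMM scaled) for guides of 12 genes in each of the 6 libraries, with points for libraries and bars for group means at day 0 (grey), day 5 (orange) and day 8 (red). Guides of Zfp207 stand at 1.19 at day 0, 9.47 at day 5 and 13.52 at day 8, whereas those of Lrrc8a do not pass the test at either time.

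Day 5 against day 0 asked which guides gained or lost share early in the selection. Guides against Zfp207, a zinc finger protein that binds Bub3 and spindle microtubules, rose from 1.19 ± 0.25 to 9.47 ± 0.09 log2 CPM (SD, n = 2), a median fold change over its 5 guides of 8.63 log2 (SD over guides 1.05). Guides against its partner Bub3, a mitotic checkpoint protein, rose from 1.42 ± 0.21 to 7.79 ± 0.04 (SD, n = 2). All 3 U1-specific proteins rose with them. Snrpc changed by 8.46 log2 (SD over guides 2.40), Snrnp70 by 5.84 (1.76) and Snrpa by 5.70 (2.72). Each of these 5 genes was higher in both day 5 libraries than in both unselected libraries and had a permutation p of 5e-07, the smallest the random draws can give (adjusted p = 0.000343). Their guides lie within 1 kb of an end of each gene in mm10, for Zfp207 on chromosome 11 from 80383310 to 80383532, for Bub3 on chromosome 7 from 131560403 to 131560454, for Snrpc on chromosome 17 from 27840102 to 27840285, for Snrnp70 on chromosome 7 from 45395393 to 45395699 and for Snrpa on chromosome 7 from 27195891 to 27196143.

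The nuclear exosome, which degrades unstable nuclear transcripts, was the list with the smallest p at day 5 in the rank test at preset correlation. Of its 19 tested members and cofactors, 8 rose over all genes and 14 when adjusted over the list alone, with a list median of 1.67 log2 (camera adjusted p = 1.74e-12). The exosome helicase Skiv2l2 (Mtrex) rose by 6.51 (SD over guides 2.89) and its partner Zfc3h1 by 4.37 (1.45). C1d rose by 3.11, Mphosph6 by 2.62 and the core subunit Exosc4 by 2.02. The cap-binding proteins Ncbp1 and Ncbp2 rose by 4.48 and 1.84. They belong with Srrt to the list of small nuclear RNA transcription and processing, in which 3 of 17 members rose over all genes, 5 adjusted over the list alone, and the list as a whole did not pass (adjusted p = 0.143), but did with camera without ranks (adjusted p = 0.00236). Pabpn1, a nuclear poly(A)-binding protein, rose by 4.07 (1.78) and the poly(A) polymerase Papola by 1.01. Cleavage and polyadenylation factors as a list did not pass (adjusted p = 0.742), with 2 of 20 members risen over all genes and, adjusted over the list alone, 4 risen and 3 fallen.

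Splicing factors rose unevenly. Of 19 tested Prp19 and catalytic-step factors, 6 rose over all genes and 12 adjusted over the list alone (adjusted p = 1.99e-06), among them Bcas2 by 4.13 log2 (SD over guides 1.72), Cwc15 by 3.40 and Prpf19 by 3.25. Of 22 tri-snRNP members, 3 rose over all genes and 7 adjusted over the list alone (adjusted p = 1.38e-05), led by Lsm3 at 2.41. Of 14 U1-associated factors, 4 rose over all genes and 6 adjusted over the list alone (adjusted p = 0.00112), Luc7l3 among them at 2.34. That list's call was lost with adjusted p = 0.0598 with an estimated correlation. U2 snRNP did not pass (adjusted p = 0.957), with 0 of 13 members called over all genes and, adjusted over the list alone, 1 risen and 2 fallen. The Sm ring did not pass either (adjusted p = 0.465, 3 members tested, 0 called over all genes and 0 adjusted over the list alone).

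Guides against Ascc3, Ascc2 and mRNA export factors fell at day 5. Ascc3 and Ascc2, which help to split stalled and collided ribosomes, fell from 40.4 ± 0.568 to 8.72 ± 4.64 and from 53.2 ± 9.04 to 6.20 ± 0.54 summed CPM (SD, n = 2). Trip4 of the same complex stood at −1.13 log2 and did not pass (adjusted permutation p = 0.109). Eny2, a subunit of SAGA and of the nuclear pore TREX-2 complex, fell from 21.6 ± 1.74 to 1.84 ± 0.504, and Myh9, the heavy chain of non-muscle myosin, from 72.9 ± 14.0 to 14.0 ± 0.776. The export receptor Nxf1 fell from 17.9 ± 1.94 to 0.707 ± 0.0982 and the glucose transporter Slc2a3 from 20.6 ± 3.79 to 8.04 ± 6.80. Mcm3ap, Sirpb1b and Vmn1r76 complete the 9 genes that fell. The mRNA export list shifted down (adjusted p = 0.000116, median −0.92), with Nxf1 and Mcm3ap fallen and Thoc3 risen (2.28) among 14 members over all genes, and 6 fallen and 1 risen adjusted over the list alone. Ribosome rescue and stress response genes did not shift as a list (adjusted p = 0.957), with 2 of 16 fallen over all genes and 3 adjusted over the list alone.

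Over all 19894 tested genes, 156 were enriched at day 5 and 9 depleted, against 1176 and 1129 at an unadjusted p under 0.05. Of the 156, 154 stood higher in both day 5 libraries than in both unselected ones. This order is given by 16.7% of random orders and was shown by 13.6% of all tested genes. The calls come from these same libraries, so it is no separate support. Groups of 5 non-targeting guides taken as 429 genes gave 0 calls, with 1.63% enriched and 5.59% depleted at an unadjusted p under 0.05. No guide passed in edgeR on its own: 0 of 105604 were called, 660 were higher and 644 lower at an unadjusted p under 0.05, and DESeq2 called 148 higher and 8 lower. Counts summed per gene in edgeR gave 0 calls, with 288 genes higher and 83 lower at an unadjusted p under 0.05 (Zfp207 unadjusted p = 0.000291, adjusted p = 0.536). The depletion count fell to 1 without day 5 replicate 1 and to 5 without day 5 replicate 2, and all named fallen genes but Eny2 and Nxf1 lost their calls with either left out (Nxf1 with replicate 1 left out). Slc2a3, Nxf1, Mcm3ap and Sirpb1b also lost them with either day 8 library left out of the shared fit. All fallen genes but Ascc2, Ascc3 and Myh9 lost them with a filter at a mean of 50 counts. Mcm3ap, Slc2a3 and Vmn1r76 also lost them without unselected replicate 1. A ranking in the manner of MAGeCK kept 4 of the 9 (Ascc2, Ascc3, Eny2 and Myh9). Of the risen genes named for day 5, Nelfcd lost the call without day 5 replicate 1, Papola without day 5 replicate 2 and Srrt without either.

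Of the other lists at day 5, the cytosolic ribosome shifted up (adjusted p = 0.00101), with 4 of 61 tested members risen over all genes and 10 adjusted over the list alone. Integrator, which processes small nuclear RNAs, also shifted up (adjusted p = 0.0057) with 0 of 14 members called over all genes and 3 adjusted over the list alone. Its call was lost with adjusted p = 0.129 with an estimated correlation. The 1071 olfactory receptor genes, which stem cells do not express, shifted slightly down (adjusted p = 0.00674, median −0.33, 0 called over all genes and 0 adjusted over the list alone), a call that was lost without day 5 replicate 1. The U1-specific list passed with 3 of 3 members over all genes and 3 adjusted over the list alone (adjusted p = 3.54e-09). The pair Zfp207 and Bub3 passed with 2 of 2 on both counts (adjusted p = 1.39e-06), which is not independent evidence, since the series title names Zfp207. In all, 8 lists shifted up, 2 shifted down and 18 did not pass, and 8 of the 10 calls held with an estimated correlation. The call of the cytosolic ribosome was lost with a filter at a mean of 50 counts, where 1 member was risen over all genes, and 2 were without day 5 replicate 1. Camera without ranks kept all 10 calls. U1-associated factors had 1 member risen over all genes without day 5 replicate 1 and 2 without day 5 replicate 2 or unselected replicate 1. Export factors had 0 fallen with that filter, without day 5 replicate 1 or without day 8 replicate 1, and 1 without unselected replicate 1, day 5 replicate 2 or day 8 replicate 2. Ribosome rescue had 0 fallen and tRNA synthetases 0 risen without either day 5 library, and cleavage and polyadenylation had 1 risen without day 5 replicate 2.

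**Figure D2:**
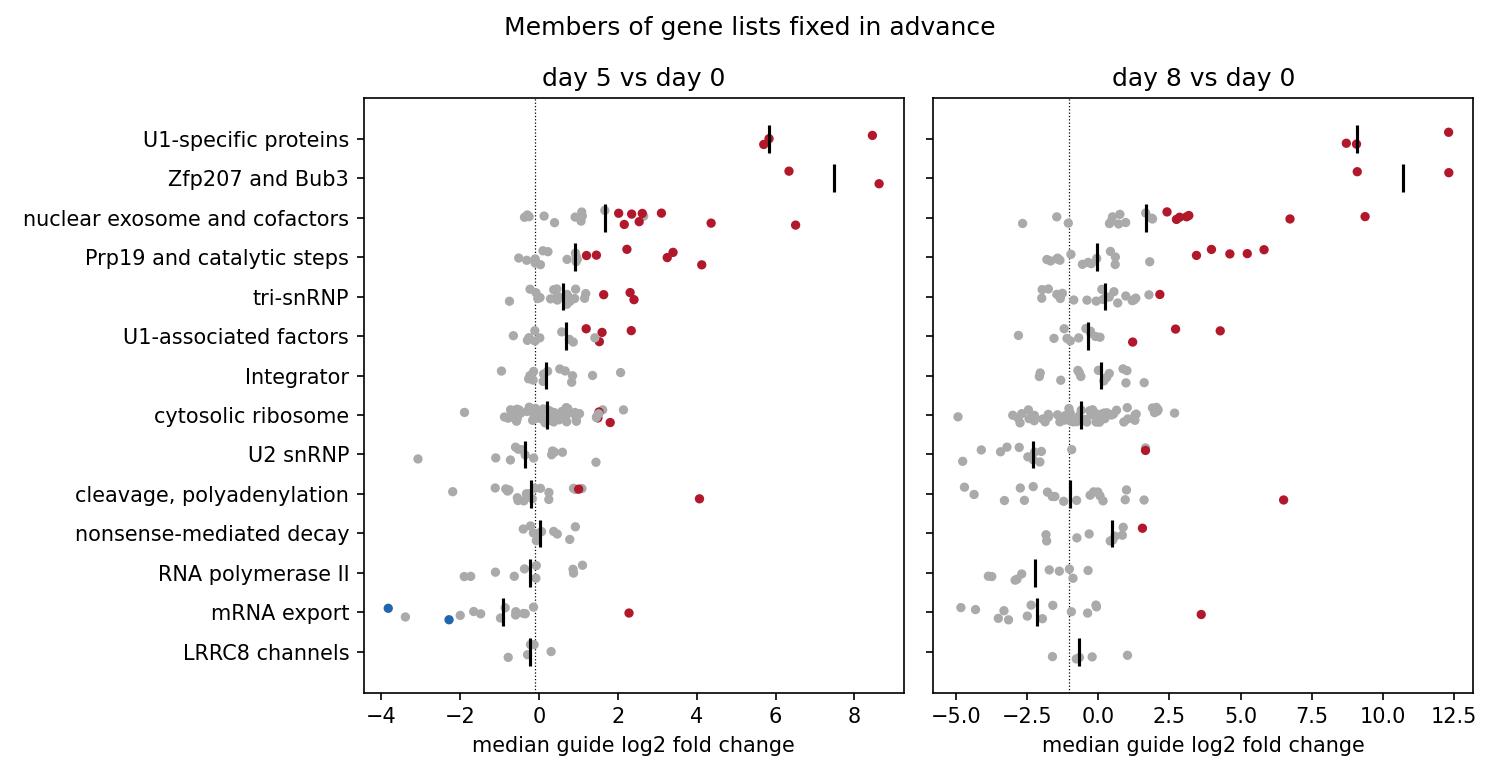
Median guide log2 fold change of each tested member of 14 gene lists at day 5 (left) and day 8 (right) against day 0. Red marks members called enriched, blue called depleted and grey no call. A black bar marks the list median and a dotted line the median of all tested genes. The U1-specific median stands at 5.84 at day 5 and 9.08 at day 8, against −0.10 and −1.02 for all guides.

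The remaining lists did not pass at day 5. Over all genes, 1 of 25 RNA polymerase II elongation factors was called (Nelfcd, 1.66 log2), as was 1 of 17 tRNA synthetases, and adjusted over the list alone the counts were 5 and 2 (adjusted p = 0.225 and 0.179). Nonsense-mediated decay, SMN assembly, the proteasome and chromatin silencing had 0 calls over all genes and, adjusted over the list alone, 3, 2, 6 and 3 risen (adjusted p = 0.185, 0.2, 0.347 and 0.604). Mediator had 1 member fallen and p53 with growth brakes and pluripotency 1 risen each when adjusted over the list alone, with 0 over all genes (adjusted p = 0.359, 0.494 and 0.581). RNA polymerase II, fibroblast markers, and neural and endoderm markers had 0 calls on both counts (adjusted p = 0.957, 0.464 and 0.604). LRRC8 channels, through which blasticidin can enter cells, also had 0 of 5 called on both counts (adjusted p = 0.957). Lrrc8a stood at 0.31 log2 (SD over guides 0.46) and Lrrc8d at −0.12 (0.68). The median and the direction of the test pointed opposite ways, relative to all guides, for cleavage and polyadenylation, LRRC8 channels, pluripotency and ribosome rescue.

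Day 8 against day 0 asked the same after longer selection. Guides against Zfp207 reached 13.52 ± 0.13 log2 CPM and those against Snrpc 13.39 ± 0.13 (SD, n = 2), a median change of 12.32 log2 in both genes (SD over guides 1.44 and 3.17). Zfp207 guides alone made up 5.81% ± 0.391 of all day 8 counts and Snrpc guides 7.35% ± 0.282 (SD, n = 2). Bub3 rose by 9.10 log2 (SD over guides 0.49), Snrpa by 9.08 (4.35) and Snrnp70 by 8.72 (2.85). The exosome helicase Skiv2l2 rose by 9.38 (4.45), Zfc3h1 by 6.74 (2.24), Pabpn1 by 6.51 (2.52) and Ncbp1 by 6.19 (3.39). Each of these 9 genes was higher in both day 8 libraries than in both unselected ones, with a permutation p of 5e-07, the smallest the draws can give (adjusted p = 0.00051).

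The nuclear exosome was again the list with the smallest p in the rank test at preset correlation (adjusted p = 7.7e-11). The list had 7 of 19 members risen over all genes and 10 adjusted over the list alone. It held at adjusted p = 0.0428 with an estimated correlation, and 4 members were risen over all genes without day 8 replicate 2. The 3 U1-specific proteins rose on both counts (3 over all genes and 3 adjusted over the list alone, adjusted p = 2.89e-09), with adjusted p = 0.0608 with an estimated correlation. The pair Zfp207 and Bub3 passed with 2 of 2 on both counts (adjusted p = 1.39e-06), again not independent evidence, with adjusted p = 0.0611 with an estimated correlation. Prp19 and catalytic-step factors shifted up relative to all guides (adjusted p = 0.000742, list median −0.06), with 5 of 19 risen over all genes and 8 adjusted over the list alone, among them Bcas2 by 5.83, Dhx16 by 5.24 and Prpf19 by 4.62. The tri-snRNP list shifted up (adjusted p = 0.000433) with 1 of 22 risen over all genes, Lsm3 by 2.16, and 6 adjusted over the list alone. Both of these calls were lost with adjusted p = 0.0611 with an estimated correlation. Without day 8 replicate 2, 0 tri-snRNP members were risen over all genes, and without day 8 replicate 1, 2 were.

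Integrator at day 8 shifted up (adjusted p = 0.00538) with 0 of 14 called on both counts, and nonsense-mediated decay (adjusted p = 0.00644) with 1 of 10 risen over all genes, Upf3b by 1.55, and 2 adjusted over the list alone. RNA polymerase II subunits shifted down (adjusted p = 0.0238) with 0 of 10 called on both counts. These calls were lost with adjusted p = 0.129, 0.111 and 0.169 with an estimated correlation, and that of RNA polymerase II also with a filter at a mean of 50 counts. Without day 8 replicate 2 the number of lists that shifted went from 8 to 5, with the 3 of this paragraph lost, and without day 8 replicate 1 it went to 6, with nonsense-mediated decay and RNA polymerase II lost.

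Among the 20 lists that did not pass at day 8, adjusted p ran from 0.058 to 0.987. Over all genes, U1-associated factors had 3 of 14 risen (Luc7l3 among them, by 4.28) and 4 adjusted over the list alone (adjusted p = 0.0762), and 1 was risen over all genes without either day 8 library. As a list they passed as higher with camera without ranks (adjusted p = 0.0104) and with a filter at a mean of 50 counts. Small nuclear RNA transcription and processing also passed as higher without ranks (adjusted p = 0.0363). The mRNA export list leaned down (adjusted p = 0.058), with 1 of 14 risen over all genes, Thoc3 by 3.62, 0 fallen, and 1 of each adjusted over the list alone. It passed as lower with the replicate block, with DESeq2 size factors and without unselected replicate 2. U2 snRNP had 1 of 13 risen over all genes, U2surp by 1.66, and 0 fallen, with 2 risen and 1 fallen adjusted over the list alone (adjusted p = 0.325, leaning down). U2surp lost its call when any 1 of the 6 libraries was left out. It also lost the call with the replicate block and with DESeq2 size factors. Olfactory receptors passed only with an estimated correlation (adjusted p = 0.168 preset, adjusted p = 0.0349 with an estimated correlation). LRRC8 channels had 0 of 5 called on both counts (adjusted p = 0.302), with Lrrc8a at 1.02 log2 (SD over guides 2.23) and Lrrc8d at −0.22 (0.90).

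Ascc2 was the 1 gene depleted at day 8 (adjusted permutation p = 0.0398), from 53.2 ± 9.04 to 1.98 ± 2.08 summed CPM (SD, n = 2; on library totals, where the median guide stood at −2.47 log2), with no count in either library for 4 of its 5 guides. The call was lost without unselected replicate 2, day 8 replicate 1 or day 8 replicate 2, and with a filter at a mean of 50 counts. Myh9 stood at 1.06 ± 1.21 summed CPM against 72.9 ± 14.0 at day 0 and did not pass (SD, n = 2, adjusted permutation p = 0.159). Eny2 had no count of any of its 5 guides, which allows up to 0.309 and 0.384 CPM per guide in the 2 libraries, and did not pass (adjusted permutation p = 0.311). Sap25, Tmem121 and Pparg came next and did not pass (adjusted permutation p = 0.292, 0.311 and 0.311).

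Over all genes, 73 were enriched at day 8 and 1 depleted. Of the 73, 72 stood higher in both day 8 libraries than in both unselected ones (3.16% of all tested genes did). The calls come from these same libraries, so the order is no separate support. Median changes of the enriched genes ran from 1.21 to 12.32 log2. No guide passed in edgeR on its own: 0 of 105604 were called, 3373 were higher and 11726 lower at an unadjusted p under 0.05, and DESeq2 called 1363 higher and 3892 lower. Counts summed per gene in edgeR gave 0 calls, with 1446 genes higher and 1079 lower at an unadjusted p under 0.05 (Zfp207 adjusted p = 0.0888). The 73 became 42 without day 8 replicate 2, and genes such as Casc3, Lsm3, U2surp, Upf3b, Taf1 and Taf8 then lost their calls.

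The genes enriched at both times numbered 65, against 0.572 for independent draws. Such draws leave out of account the shared unselected libraries and any cells carried over from day 5 to day 8. The 65 include Zfp207, Bub3, the U1-specific proteins, Skiv2l2, Zfc3h1, Ncbp1, Pabpn1 and Bcas2. Outside the lists they include Taf2 (4.89 log2 at day 5 and 5.43 at day 8) and Ppwd1 (4.11 and 4.59). Others outside the lists, chosen after their values were seen, were Actb (3.33 and 4.47), Eif3d (3.17 and 4.40) and Casc3 (2.48 and 3.53). Chosen in the same way were the ubiquitin ligases Rnf20 (2.40 and 2.05) and Rnf40 (2.73 and 2.97) and 1110037F02Rik (Virma, 2.62 and 4.08), a component of the RNA methylation complex. Both comparisons share the unselected libraries, and dividing these would leave 1 library for each. Across guides, which are not independent replicates, the covariance of the 2 fold changes was 0.606, against 0.062 in simulated unchanged cells with shared controls. The simulated libraries were drawn independently. The 0.062 therefore leaves out any cells carried over from day 5 to day 8 (values of equal number correlated at 0.172 after removal of group means). Selection at both times and such carry-over cannot be told apart here. A further 8 genes were called at day 8 and not at day 5: Cask, Ddx59, Gm996, Rbm17, Smu1, U2surp, Upf3b and Utp3. All 8 lost the day 8 call without day 8 replicate 1, and all but Ddx59 without day 8 replicate 2. Upf3b also lost it without either unselected library, Rbm17 without unselected replicate 1, Cask, Smu1 and Utp3 without unselected replicate 2, and Cask, Gm996, Rbm17 and Utp3 without either day 5 library. With the replicate number as a block, Cask, Gm996, U2surp and Utp3 lost the day 8 call too. A ranking in the manner of MAGeCK lost the day 8 call of all of them but Gm996, Ddx59 included. None of these 8 genes passed the test of day 8 against day 5, so a difference between the times was not shown for them.

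**Figure D3:**
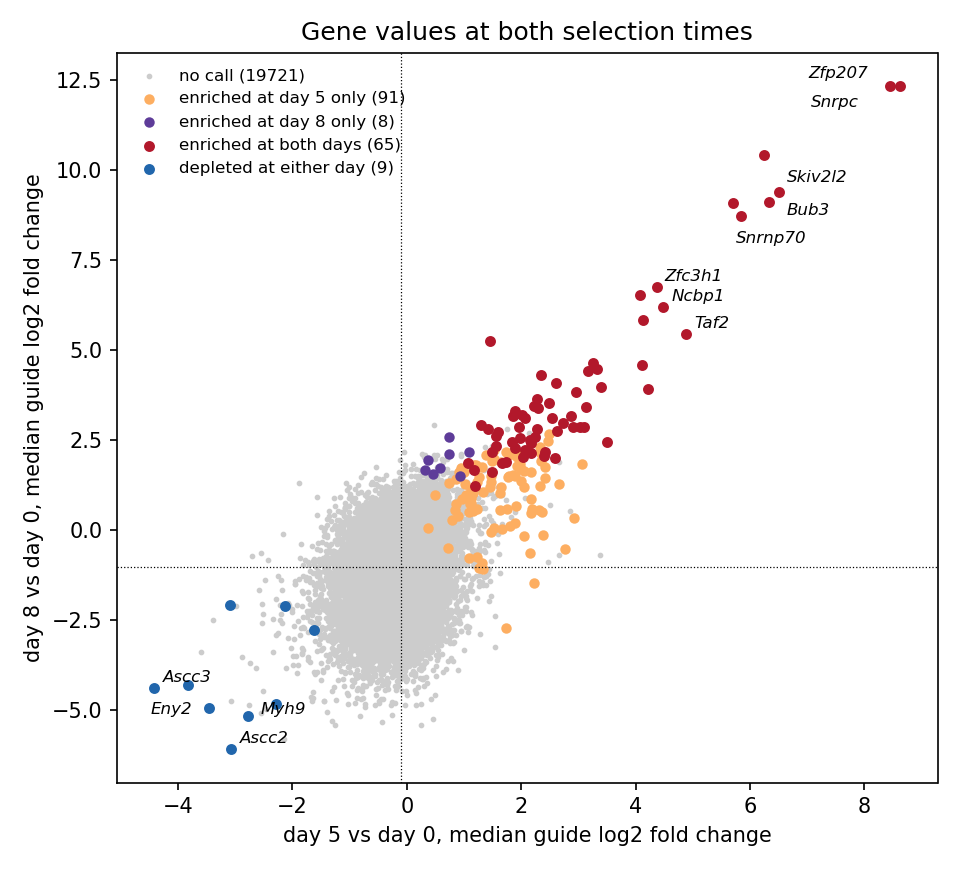
Median guide log2 fold change of each tested gene at day 5 (horizontal) and day 8 (vertical) against day 0, coloured by call. Dotted lines mark the medians of all tested genes. The 65 genes enriched at both times reach 8.63 at day 5 and 12.32 at day 8, both at Zfp207.

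Day 8 against day 5 tested what changed between the selected times, where the median guide stood at −0.83 log2. Guides against Snrpc rose further by 4.47 log2 (SD over guides 0.98), Zfp207 by 3.76 (0.54), Snrpa by 3.43 (1.65) and Snrnp70 by 3.15 (1.12). Bub3 rose by 2.68 (0.25), Zfc3h1 by 2.63 (0.82) and Pabpn1 by 2.27 (0.80). With Bcas2, BC024978 and 1110037F02Rik they make up the 10 genes enriched at day 8 over day 5. The U1-specific list rose with 3 of 3 members over all genes and 3 adjusted over the list alone (adjusted p = 1.1e-08), Zfp207 and Bub3 with 2 of 2 on both counts (adjusted p = 2.37e-06, not independent evidence) and the nuclear exosome with 1 of 19 over all genes and 3 adjusted over the list alone (adjusted p = 0.00157). All 3 list calls were lost with adjusted p = 0.165 with an estimated correlation, and the other 25 lists did not pass. The estimates were −0.0337, −0.0676 and 0.0019, below the preset 0.01, so a higher correlation was not the cause of these losses.

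No gene was depleted at day 8 against day 5 in the rank test on edgeR values: 0 passed, and 1053 had an unadjusted p under 0.05. The smallest depletion p were those of Tmem121, Clec2d and Grm3, which did not pass (adjusted permutation p = 0.279, 0.279 and 0.675). Tmem121, a membrane protein gene, stood at 40.5 ± 7.85 summed CPM at day 5 and 0.706 ± 0.456 at day 8 (SD, n = 2), on library totals, where the median guide stood at −2.05 log2 between these times. No guide passed in edgeR on its own: 0 of 105604 were called, 2522 were higher and 10939 lower at an unadjusted p under 0.05, and DESeq2 called 791 higher and 3120 lower. Counts summed per gene in edgeR gave 0 calls (1060 higher and 1030 lower at an unadjusted p under 0.05), and a ranking in the manner of MAGeCK gave 17 enriched genes. The 10 enriched genes became 0 without day 5 replicate 1 or without day 8 replicate 2, 2 without day 5 replicate 2 and 5 without day 8 replicate 1. Snrpa and BC024978 lost their calls without the guides listed under 2 genes, and Pabpn1, Bcas2 and 1110037F02Rik without either unselected library. Over all genes, the U1-specific members called became 0 without either day 5 library or without day 8 replicate 2.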

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

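Of the tests in this part, those of single guides at day 8 and of guides shared by Snrpa and BC024978 were chosen after the result was seen, and the tests of neighbouring promoters and of distant BC024978 guides were fixed before it.

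The direct test of day 8 against day 5 singled out 10 genes and 3 gene lists as differing between the selected times. The further rise was 4.47 log2 for Snrpc, 4.17 for BC024978, 3.76 for Zfp207, 3.43 for Snrpa, 3.15 for Snrnp70, 2.68 for Bub3, 2.63 for Zfc3h1, 2.27 for Pabpn1, 1.70 for Bcas2 and 1.46 for 1110037F02Rik, where the median guide stood at −0.83. For the lists, adjusted p was 1.1e-08 for U1-specific proteins, 2.37e-06 for Zfp207 and Bub3 and 0.00157 for the nuclear exosome, and each of these 3 calls was lost with adjusted p = 0.165 with an estimated correlation. The gene count became 0 without day 5 replicate 1 or day 8 replicate 2, 2 without day 5 replicate 2 and 5 without day 8 replicate 1. Without the guides listed under 2 genes, an alternative added later, the calls of Snrpa and BC024978 between the selected times were lost.

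Many of the most abundant day 8 guides belong to genes with no call: of the 100 top guides of each day 8 library, 125 guide and library pairs were of this kind, and they took 31.6% and 30.5% of the counts of the 2 libraries. Zc3h3, with 2 guides raised in both libraries, held 15.9% and 20.6% of all counts among these. A jackpot of amplification in 1 library is argued against, since 113 of the 125 (90.4%) already stood at least 4 times over day 0 in the day 5 library of the same number. Of the 125, 16 (12.8%) were raised in the other day 8 library, against 74 of 75 pairs (98.7%) of called genes. This contrast is partly built in, since calls favour guides raised in both libraries. The 4-fold bar was also stricter at day 8, since on library totals the median day 8 guide stood at −2.47 log2. Within these limits, activity of the guide itself is argued against for most of these guides by number. It is not argued against for those 16, which include the Zc3h3 guides. A resistant clone in 1 culture, a reading that takes equal numbers at day 5 and day 8 for 1 culture although the labels do not say so, stays open for the rest, since 15 (12.0%) were raised in the day 5 library of the other number and 2 (1.6%, exact interval 0.19 to 5.66) were non-targeting, against 2.01% of the table.

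BC024978 rose by 6.25 log2 at day 5 and 10.42 at day 8 and shares the positions of 2 guides with its neighbour Snrpa. Counts of shared guides as the whole cause of the rise over day 0 are argued against, since its other 3 guides still gave 9.93 at day 8 (adjusted permutation p = 0.000508). Repression of the Snrpa promoter by guides placed for BC024978 and a function of BC024978 of its own cannot be told apart here. For the former, 2 of 36 other genes with guides within 1 kb of an enriched gene's guides had an unadjusted p under 0.05 (5.6%, exact interval 0.7 to 18.7, all genes 5.93%), too few to decide. For the latter, 0 guides of BC024978 lie over 1 kb from every Snrpa guide (the farthest is 90 bp away), so its own function has no separate reading.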

How the results depend on the processing

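Among these settings, the fit of only the 2 groups compared (for gene counts) and the fit without guides listed under 2 genes were chosen after seeing the data. Genes enriched at day 5 (156) and at day 8 (73) stayed within 1.5 times those counts under the DESeq2 scaling, other filters, rank limits, rankings and thresholds, with the block and in the added settings. The overlap (65) was run with the MAGeCK manner of ranking (53), a threshold of 0.1 (79), the block and the leave-outs. Exceptions were counts summed per gene in edgeR, which gave 0 enriched genes in each of the 3 comparisons and 0 depleted, and day 8 replicate 2 left out (42 at day 8, 41 at both). The DESeq2 scaling gave 159 and 68. The members called changed as well as their number. The MAGeCK manner of ranking kept 104 of the 156 genes and 52 of the 73. A filter at a mean of 50 counts kept 112 and 66. Of 1782 values of named genes under alternatives, 1580 kept their direction and side of the threshold, 202 kept the direction and lost the call, and 0 reversed. Of the 202, 101 came from counts summed per gene.

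DESeq2 in place of edgeR gave 148 enriched and 8 depleted guides at day 5, 1363 and 3892 at day 8, and 791 and 3120 between them. For day 8 depletion, a ranking in the manner of MAGeCK gave 4 genes, a mean of at least 50 counts 0, the 2 groups compared 3 and the replicate block 2, in place of 1. The mean of at least 50 counts gave 3 depleted genes at day 5 in place of 9, and the MAGeCK manner gave 17 enriched genes for day 8 against day 5 in place of 10. Lists shifted were 2 in place of 8 at day 8 and 0 in place of 3 between the selected times with an estimated correlation, and 11, 10 and 3 with camera without ranks. For all of these the cause was not tested. For the 3 lists between the selected times, the estimated correlations lay below the preset 0.01. So did those of the lists lost at day 5 and at day 8, apart from RNA polymerase II at day 8 (0.0199). Where they did, a higher correlation was not the cause.

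Leaving out 1 library at a time gave 106 to 154 enriched and 1 to 12 depleted genes at day 5, 42 to 75 and 0 to 3 at day 8, and 0 to 7 and 0 to 1 for day 8 against day 5. The overlap ran from 41 to 70 and the lists shifted from 9 to 10, 5 to 9 and 3 to 4. Guides ran from 0 to 8197 enriched and 0 to 17818 depleted at day 8, from 0 to 6896 and 0 to 17030 against day 5, and stayed at 0 to 0 at day 5. The high values come without day 8 replicate 1 or 2, where the lone day 8 library is assumed to vary like the other groups although the day 8 pair varied most (141% against 23.1% at day 0).

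With the replicate number as a block, 152 genes were enriched and 11 depleted at day 5, 71 and 2 at day 8, and 10 and 0 between them, with 69 enriched at both. The block kept 135 of the 156 genes enriched at day 5 in the main fit and 67 of the 73 at day 8. Values of equal number, after removal of group means, correlated at 0.098 (day 0 and day 5), 0.058 (day 0 and day 8) and 0.172 (day 5 and day 8), and the labels do not say what a number shares. As a hint from the data, 113 of the 125 abundant day 8 guides of uncalled genes were raised in the day 5 library of the same number and 15 in that of the other number. At day 8 the median guide had 14 counts in both libraries and 19.7% and 19.5% of guides had none, and the test on simulated counts recovered 1 of 50 genes lowered 4-fold, so that moderate falls were not detectable there.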

Other observations

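The test of slow growth was chosen after the result was seen, and the test of low counts was fixed before it. TFIID, eIF3 and INO80 were picked because their subunits were seen among the enriched genes, so a test of enrichment would run on the calls that prompted it, and only counts are given. Of 14 tested subunits of TFIID, the general factor that binds core promoters, 7 rose at day 5 (Taf1, Taf2, Taf3, Taf5, Taf6, Taf8 and Taf12) and 4 at day 8 (Taf1, Taf2, Taf6 and Taf8), with Taf2 at 4.89 log2 (SD over guides 3.11), Taf6 at 4.22 (1.86) and Taf1 at 2.88 (1.23) at day 5. Without day 8 replicate 2, Taf1 and Taf8 lost their day 8 calls, which left 2. At day 5, Taf12 lost its call without either day 5 library and Taf3 without day 5 replicate 2. A ranking in the manner of MAGeCK lost Taf5 at day 5 and Taf6 and Taf8 at day 8. Guides ranked by log2 fold change also lost Taf8 at day 8.

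Translation initiation factor eIF3 had 3 of 13 tested subunits enriched at day 5 (Eif3d, Eif3e and Eif3h) and 2 at day 8 (Eif3d and Eif3h). Eif5a and Dhps, which acts in making the hypusine residue of Eif5a, were also chosen after their values were seen. They rose at day 5 by 2.03 (SD over guides 0.69) and 1.98 (0.98). The chromatin remodeller INO80 had 3 of 14 enriched at day 5 (Ino80e, Actr8 and Nfrkb) and 2 at day 8 (Ino80e and Nfrkb). Actr8 lost its call without day 5 replicate 2 and Eif3e with a filter at a mean of 50 counts.

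Zc3h3, a zinc finger protein gene chosen after its values were seen, held 18.2% ± 3.29 of day 8 counts and 1.07% ± 0.0142 of day 5 counts (SD, n = 2), more than any named gene. Most of this came from 2 of its 5 guides, which stood among the 11 guides of uncalled genes raised in both day 8 libraries. It did not pass at day 5 (adjusted permutation p = 0.0917) or day 8 (adjusted permutation p = 0.214).

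Genes enriched at day 5 started low: their median day 0 level was −1.13 log2 relative to non-targeting guides, against −0.10 for all tested genes. Of 878 genes at or below −1, 9.45% were enriched, against 0.38% of the other 19016. A median rise from low counts by themselves is argued against, since 254 low non-targeting guides differed from the others by −0.049 log2 at day 5 (bootstrap interval −0.295 to 0.103). Gene calls rest on guide ranks, and low non-targeting guides were not grouped into genes. Whether low counts raise the share of calls was therefore not tested. Survival of any slowly growing cell and an action of the enriched genes on the reporter cannot be told apart, since no group of slow cells without such an action is in the design. As a first check, 29 proteasome, RNA polymerase II and tRNA synthetase genes that started low had a median of 0.35 (SD 1.32), 0.195 above the 849 other low genes (bootstrap interval −0.136 to 0.799, permutation p = 0.304), too wide an interval to decide.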
